A study of Caenorhabditis elegans with 2 samples.

How the data were processed

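Small RNA was sequenced from young adult hermaphrodites of the nematode Caenorhabditis elegans in 2 libraries, 1 from the wild-type strain N2 and 1 from small RNA that came down with HRDE-1. HRDE-1 is an Argonaute protein of germline nuclei that binds small interfering RNAs. Per the labels' protocols, a FLAG and StrepII tagged HRDE-1 was pulled from worm lysate with an anti-FLAG resin, and its RNA was cloned by a procedure that does not need a 5′ monophosphate, so that RNAs made by RNA-dependent RNA polymerases are captured. The labels give the same protocol text for both libraries and do not say whether the N2 library is small RNA of the whole lysate or a mock pull-down from untagged worms. The ratio of the libraries therefore compares the pull-down with N2 small RNA of unstated preparation.

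The deposited signal is a coverage value per 1 kb bin and library over chromosomes I to V and X, 100257 bins in all. Per the submitters' processing notes, Bowtie 0.12.7 was used; the genome build, read filters, treatment of reads with several sites and normalising total are not given in the sources used here. From the values, every bin carries a floor of 0.1, and the value of 1 read above that floor was 0.232 in N2 and 0.169 in the coIP, as a scale of 1000000 reads would give for about 4305565 and 5919559 reads. Of the values above the floor, 62.9% in N2 and 36.4% in the coIP lay within 0.0055 of a whole number of reads, and the others held fractions, as reads shared between several sites would give. The bins therefore hold read equivalents, not counts, and no count test was run. The read equivalents in the bins were 2161953 for N2 and 4833045 for the coIP, or 50.2% and 81.6% of the inferred normalising totals.

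The deposited table also holds the authors' p-value per bin, rounded, with a method that the sources do not state, and the authors' marks GRTS and GRH per bin. Neither abbreviation is spelled out in the file. In published work on HRDE-1 they stand for loci under germline nuclear RNAi-mediated transcriptional silencing (GRTS) and heterochromatin (GRH, with methylation of histone H3 at lysine 9). How the marks were assigned is not stated, so they may have been chosen with the help of related small RNA data.

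The last bin of chromosome V ended at 20920000, before the end of the last gene annotated on V in the reference assembly WBcel235, and the bins of I stopped at 15060000, also short of its last annotated gene, while the other chromosomes did not stop short. An older build would give this on V, and bins left out at chromosome ends would give it on both, so the build could not be matched to the reference. Coordinates were not converted. For that reason the 18 gene lists fixed beforehand (among them small RNA pathway, spermatogenesis, microRNA, piRNA, transposon protein and LTR-like intervals), the value of the hrde-1 gene, and gene names for regions were not run, and regions are given by the position in the file.

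Each library was divided by its own sum and set to parts of 1000000 (ppm). A bin was measured when the mean of both libraries reached 0.351 ppm, the median of all values, and log2 ratios of coIP over N2 were taken after adding a pseudocount of 0.121 ppm, the smallest value; they understate the change of low bins. With 1 library per group there is no replicate, no test between groups and no p-value here. Bins at least 4-fold higher or lower were counted instead. Shares of a library were computed with the floor subtracted. The median log2 ratio of the marked bins was placed among 10000 random lists of the same size matched in 20 classes of mean signal, as a description of these libraries. All intervals are at 95%. Those of ratios and shares treat read equivalents as counts and cover counting error only. Those of medians give the uncertainty of the median with bins taken as independent, so they may be too narrow where bins lie in runs. A value of 0 reads allows up to 3 reads.

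The text names, by a rule fixed before the data were examined, the 10 runs of higher bins (gaps of up to 1 bin bridged) with the largest coIP signal, the 10 runs of at least 2 bins with the largest ratio and the 5 runs of lower bins with the largest N2 signal. The intervals of the LTR retrotransposons Cer3 and Cer8 were added after the data were examined: each starts at the position known for the element and extends over adjacent bins of at least 10 ppm in the coIP. That position was not matched to the file's build, so the names of these intervals are not certain. The windows for the piRNA clusters of IV, 5 to 7 and 14 to 17 Mb, were also added then, as was the use of the marks as lists. The measured-bin counting was tested on simulated data with Poisson noise at these depths. The simulation took the N2 reads as the true level of both libraries. Bins with N2 at the floor therefore stayed empty and could not pass, so the test does not cover higher bins with N2 at the floor. The 8-fold changes were placed in bins of at least 1 N2 read and scored whether or not the bin was measured. Of 49384 unchanged measured bins, 609 passed the 4-fold rule as higher and 652 as lower, and of the simulated 8-fold changes 90.0% of increases and 64.0% of decreases passed. At 10 times the minimum, 12 and 91 of 20467 unchanged bins passed, and 100.0% and 96.0% of 8-fold changes, here placed in bins of at least 10 N2 reads.

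Alternatives were another fold threshold (2-fold, 8-fold), scaling by the median of ratios, pseudocounts 10 times larger or smaller, no minimum or 10 times the minimum, shares without the top 10 bins of either library, and arms as the outer 20% in place of 30% of each chromosome. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and scikit-learn 1.9.0, and plots drawn with matplotlib 3.10.9.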

Results

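The series addresses where small RNAs bound by HRDE-1 map in the genome, in a study of retrotransposon transcripts under nuclear RNAi. It holds 1 library of N2 small RNA and 1 library of small RNA from the HRDE-1 pull-down (coIP), both from young adult hermaphrodites, without replicates. The bins held 2161953 read equivalents in N2 and 4833045 in the coIP. Of 100257 bins of 1 kb, 42.9% in N2 and 20.97% in the coIP were at the floor, that is, without a read. No replicate error exists for any difference below. The intervals of ratios and shares cover counting error only, and those of medians take bins as independent.

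The N2 library was dominated by a few places and the coIP library was not. The 10 highest bins took 40.995% of the N2 signal against 4.02% of the coIP signal, and the highest bin alone took 10.1% and 0.533%. The top 1% of bins (1003) held 79.3% of N2 and 57.0% of the coIP. The upper 50% of the signal lay in 26 bins in N2 and in 668 bins in the coIP.

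Of 58910 measured bins, 11446 (19.4%) were at least 4-fold higher in the coIP and 5326 (9.04%) at least 4-fold lower, after scaling to the library totals. The higher bins were 68.2% of these calls under that scaling, but 34.3% (5862 higher, 11204 lower) with scaling by the median of ratios and 39.0% (6852 higher, 10724 lower) with totals that leave out the top 10 bins of either library. The number of bins on either side is therefore set by the scaling. The median measured bin had a log2 ratio of 0.73 (1.66-fold) under library totals, and ratios below are to be read against that shift. It depends on the bins taken: the median was -0.12 over all 100257 bins, many of them at the floor, and 2.20 over the 3170 bins at 100 times the minimum. Of the higher bins, 3311 had N2 at the floor and 6942 had under 3 N2 reads. Among the 19299 bins at 10 times the minimum, 6306 were higher and 2277 lower. Across measured bins, which are not independent replicates, Pearson's r of the log2 values was 0.587 and Spearman's rho 0.511, against 0.225 and 0.147 at 10 times the minimum. A minimum set on the mean of both libraries lowers such values by itself, so the fall does not show poorer agreement at high signal.

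**Figure D1:**
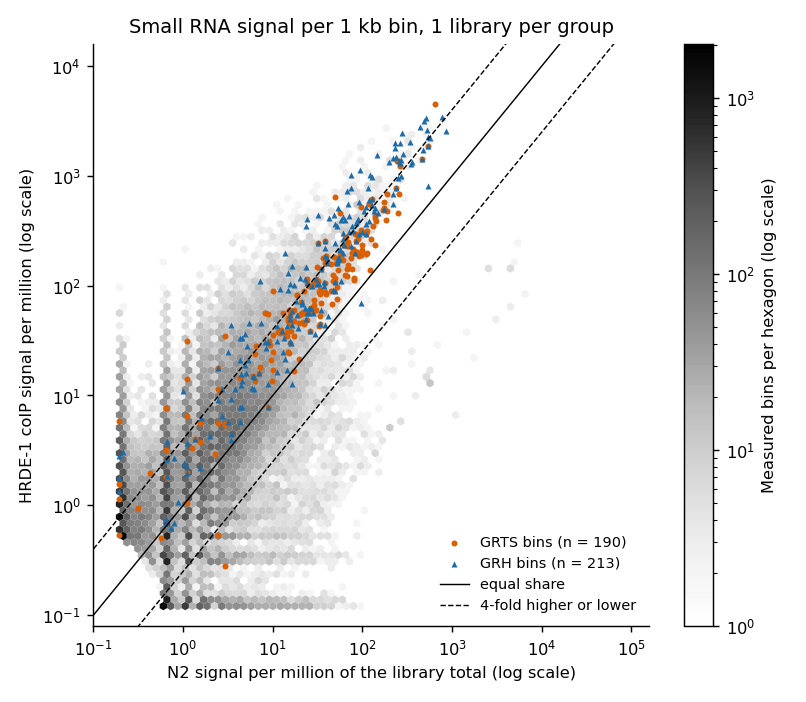
Signal of each measured 1 kb bin in N2 (horizontal, log scale) and in the HRDE-1 coIP (vertical, log scale), both in ppm (parts of 1000000) of the library total, with 1 library per group; grey hexagons count bins, orange circles are the 190 measured GRTS bins and blue triangles the 213 measured GRH bins. Solid and dashed lines mark equal signal and a 4-fold difference; the marked bins lie mostly between the solid line and a little above the upper dashed line, and most bins of very high N2 signal lie under the lower dashed line.

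In the authors' deposited table, 17428 bins had a p-value at or under 0.05, of which 12593 were higher in the coIP after scaling to library totals and 4835 lower. In the authors' deposited table those bins included 164 GRTS and 178 GRH bins, and 8673 of them also passed the 4-fold rule as higher. The p-values of the authors' deposited table were near 1 where the deposited coIP value was 1.62 times the N2 value, close to the ratio of the column sums, 1.61, so they follow the scaling to library totals.

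Bins marked as targets of germline nuclear RNAi were higher in the coIP. The 191 GRTS bins lay in 94 runs, and the 190 measured ones had a median log2 ratio of 1.45 (1.36 to 1.598), with 39 at least 4-fold higher, 1 at least 4-fold lower and 171 above the median measured bin. Their share of the library was 1.11% in N2 and 3.68% in the coIP. The 215 GRH bins lay in 104 runs, and the 213 measured ones had a median of 1.88 (1.71 to 1.98), with 90 at least 4-fold higher, 0 lower and 191 above the median measured bin. Their share went from 1.86% in N2 to 8.82% in the coIP. The 165 measured bins with the GRTS mark alone had a median of 1.41, the 188 with the GRH mark alone 1.91, and the 25 with both 1.70, against 0.73 for unmarked bins. With scaling by the median of ratios the medians were 0.72 for GRTS and 1.15 for GRH.

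Where these medians stood among other bins depended on how the other bins were chosen. Among random lists matched on the mean of both libraries, as fixed beforehand, the GRTS median was at percentile 0.57 (median of the matched lists 1.84) and the GRH median at percentile 57.0 (1.85). The GRH percentile was 84.3 with no minimum and 19.9 at 10 times the minimum. With 1 bin per run the GRTS and GRH percentiles were 5.44 and 17.5, and over bins with whole N2 reads 5.59 and 10.8, so the marks then stood closer together. Among lists matched on the N2 signal alone, a choice made after the data were seen, both were at percentile 100.0, with matched medians of 0.17.

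**Figure D2:**
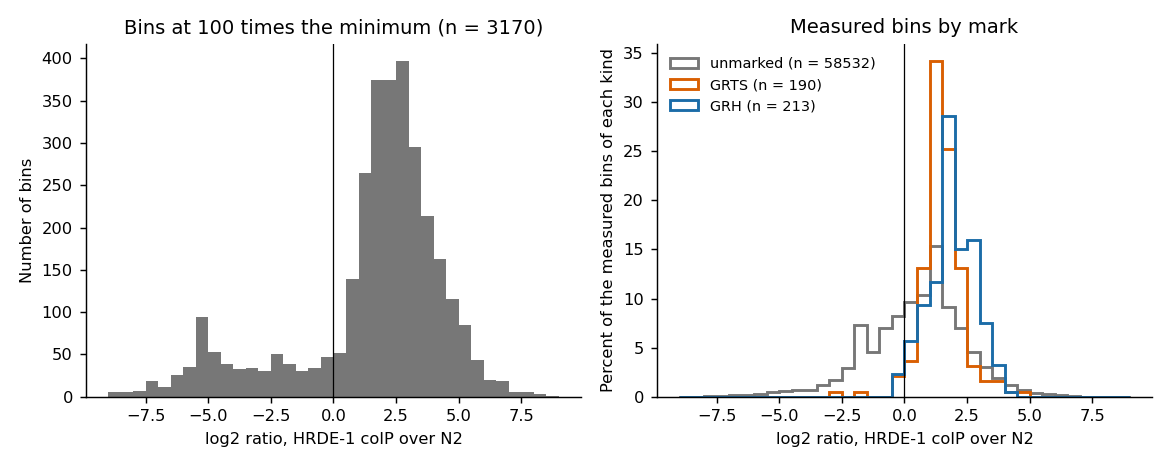
Left, number of bins per class of log2 ratio (coIP over N2, classes of 0.5) among the 3170 bins at 100 times the minimum, with most bins at positive ratios and a long stretch at negative ratios that holds a peak of 94 bins. Right, the same ratio as percent of the measured unmarked, GRTS (190) and GRH (213) bins; the medians are 0.73, 1.45 and 1.88.

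The intervals of Cer3 and Cer8, LTR retrotransposons known as targets of germline nuclear RNAi, were chosen after the data were examined. Their edges were set by coIP signal of at least 10 ppm, so adjoining bins of low coIP signal were left out of the ratios. Their names rest on positions not matched to the file's build. The Cer3 interval, chromosome IV 913001 to 922000 in the positions of the file, held 1812 ppm in the coIP (parts of 1000000 of the library total) and 643.6 ppm in N2, a ratio of 2.82, or 2.80 (2.65 to 2.97) in read equivalents with the floor subtracted, and 7 of its 9 bins carried the GRTS mark. The Cer8 interval, V 5179001 to 5193000, held 2400.2 ppm in the coIP and 920.5 ppm in N2, a ratio of 2.61, or 2.59 (2.47 to 2.72) in read equivalents, with 10 GRTS bins of 14. The GRTS marks went on past the end of the Cer8 interval, in a run from V 5187001 to 5201000. In log2 the Cer3 and Cer8 ratios were 1.49 and 1.38, and 0.76 and 0.65 with scaling by the median of ratios.

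**Figure D3:**
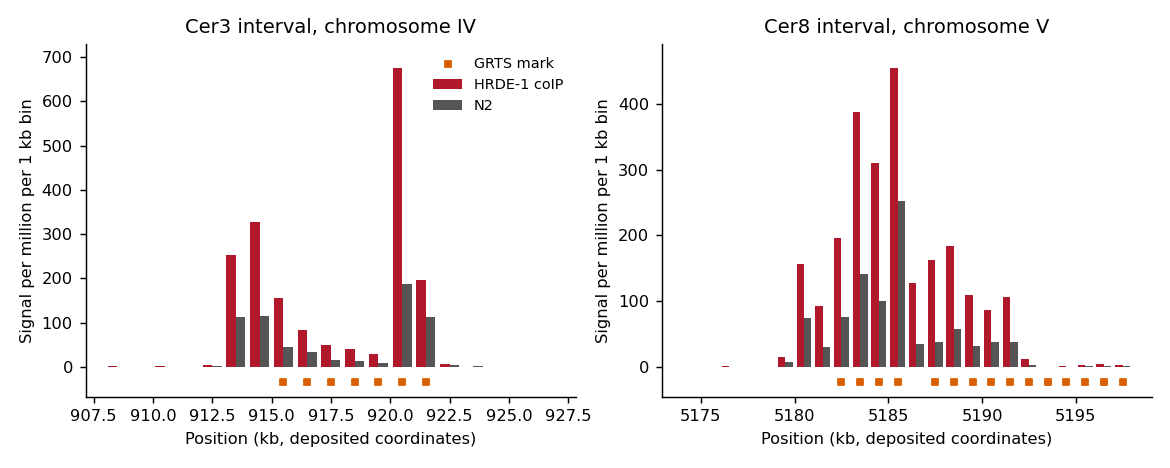
Signal in ppm of each 1 kb bin in the HRDE-1 coIP (red) and N2 (grey) over the Cer3 interval on IV and the Cer8 interval on V with 5 flanking bins on each side, at the positions of the file; orange squares are GRTS marks. The coIP bars exceed the N2 bars throughout both intervals, by 2.82 and 2.61 times in sum, but the edges of the intervals were set by the coIP signal.

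Most of the highest coIP bins carried no mark. Of the 100 highest coIP bins, 27 carried a GRTS or GRH mark and 73 carried none. Of those 73, 63 were at least 4-fold higher than N2. Of the 1000 highest, 141 were marked. Marks spread at random over all bins would give 0.380 and 3.80. Those chance values ignore signal: the median N2 signal was 30.6 ppm for GRTS, 31.3 ppm for GRH and 0.254 ppm for unmarked bins. Chance values at like signal were not computed for these counts. Of the 11446 higher bins, 123 were marked and 11323 were not, but only 381 bins carry a mark at all. Among measured bins, 32.5% of the marked and 19.3% of the unmarked were at least 4-fold higher. For GRTS bins the share was 20.5% and for GRH bins 42.3%. These shares are not matched on signal, and the share rises with signal. Over all measured bins 19.4% were higher, but at 10 times the minimum 32.7% were. That minimum was reached by 173 of the 190 GRTS bins and 193 of the 213 GRH bins. The shares of marked and unmarked bins therefore do not compare like with like. No gene is given for the regions that follow, because the file's build could not be matched to the reference annotation. Their ratios are of read equivalents with the floor subtracted, each as a share of its library.

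The 10 higher runs with the largest coIP signal held 5024 to 7963 ppm each, together 6.30% of the coIP and 0.761% of N2, and 5 of them carried a mark. The largest was X 13396001 to 13398000 with a ratio of 15.5 (14.6 to 16.5), unmarked. On I, the runs 13954001 to 13961000 and 13840001 to 13854000 had ratios of 7.39 (7.08 to 7.72), with 1 GRH bin, and 8.00 (7.65 to 8.38), unmarked. On V, 20465001 to 20470000 had 8.60 (8.19 to 9.03) with 1 GRTS and 1 GRH bin, and 310001 to 324000 had 7.03 (6.68 to 7.40) with 1 GRTS bin. On II, 11170001 to 11177000 had 4.52 (4.35 to 4.69) with 6 GRH bins, and 14141001 to 14144000 had 6.26 (5.98 to 6.55) with 1 GRH bin; with scaling by the median of ratios both fall under the 4-fold rule, at log2 1.45 and 1.93. The others, unmarked, were IV 6083001 to 6090000 with 15.5 (14.4 to 16.7), X 16790001 to 16795000 with 12.4 (11.6 to 13.3) and IV 16828001 to 16847000 with 10.5 (9.88 to 11.2).

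The 10 runs with the largest ratio were all unmarked, 4 of them on X, and rested on 0 to 18.3 N2 read equivalents. In 4 runs N2 had under 1 read. Counting 3 reads in N2, the ratio was 111.7 at V 3115001 to 3119000, 40.1 at II 923001 to 925000, 34.9 at X 17452001 to 17454000 and 30.59 at III 7842001 to 7844000. The lower limits of their counting intervals were 90.6, 32.4, 28.2 and 24.6, in that order. With about 1 to 3 N2 reads, the counting interval of the ratio was 148 to 32633 at X 14446001 to 14454000, 55.9 to 1674 at V 20717001 to 20720000, 45.9 to 653 at X 7501001 to 7503000 and 62.6 to 891 at V 8192001 to 8196000. At X 7272001 to 7281000 (13.0 N2 reads) the ratio was 147 (85.9 to 276), and at II 3271001 to 3278000 (18.3 N2 reads) it was 101 (63.7 to 170).

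The 5 lower runs with the largest N2 signal, all unmarked, held 36.7% of N2 and 0.948% of the coIP. The run III 8865001 to 8868000 held 10.5% of N2 and was 38.5-fold lower in the coIP (37.8 to 39.2). The others were III 2172001 to 2174000, 41.3-fold lower (40.5 to 42.2), V 14364001 to 14365000, 72.6-fold lower (70.6 to 74.7), V 17115001 to 17133000, 26.04-fold lower (25.5 to 26.6), and IV 14031001 to 14035000, 31.2-fold lower (30.4 to 31.9). In the V run of 18 kb, 6 bins had N2 values within 0.1% of each other (2185.8 to 2186.0 as deposited).

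The coIP signal lay more in the chromosome arms, taken as the outer 30% at each end. Arms held 53.5% of N2 (53.4 to 53.5) and 71.4% of the coIP (71.4 to 71.5), or 61.5% and 70.8% without the top 10 bins of either library. The median log2 ratio was 0.95 in arms and 0.35 in centres, which lies on the other side of 0 when set against the shift of 0.73. Chromosomes I and II held 10.3% and 9.22% of N2 but 19.3% and 19.5% of the coIP. Chromosomes III, IV and V held 25.5%, 21.2% and 22.0% of N2 and 14.4%, 16.5% and 15.3% of the coIP, and X held 11.8% and 15.0%. Without the top 10 bins of either library the order turned on III (12.7% of N2 and 14.7% of the coIP) and on X (15.7% and 14.7%), and chromosome II held 15.7% of N2 and 20.2% of the coIP. Over all measured bins, 20.6% of X bins were higher and 10.2% lower, against 19.2% and 8.85% on the autosomes, and the median log2 ratio was 0.66 on X and 0.74 on the autosomes. At 10 times the minimum, 45.8% of X bins were higher and 17.1% lower, against 31.2% and 11.2% on the autosomes. The medians there were 1.83 on X and 1.12 on the autosomes, so their order turned.

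The regions of IV known to hold most piRNA genes had low median ratios over their bins, but not low shares of the coIP signal throughout. The window at 5 to 7 Mb had a median log2 ratio of -0.23 and that at 14 to 17 Mb of -0.06, against 0.65 over the rest of IV. At 10 times the minimum these medians were 0.25, 0.92 and 1.04, so the second window then differed little from the rest of the chromosome. The first window held 1.11% of N2 and 1.88% of the coIP. Within it, the run IV 6083001 to 6090000 alone held 0.0353% of N2 and 0.547% of the coIP. The second held 6.12% of N2 and 2.85% of the coIP, or 1.19% and 2.69% without its highest N2 bin. Of 102 tiles of 1 Mb, the tile at 5 to 6 Mb of IV was the lowest, at -0.89, and 3 of the 5 tiles in the windows were among the lowest 10. Of these lowest 10, 5 were on X, outside any such window. Tile medians can rest on very few reads. The value 1.05 recurs across tiles and is the log2 ratio of a bin with 0 N2 reads and about 2 coIP reads. The value -0.23 equals that of a bin with about 1 N2 read and 2 coIP reads. It is the median of the first window and of the tiles at IV 10 to 11, X 8 to 9 and X 10 to 11 Mb. Tiles were not computed at 10 times the minimum, so their order may reflect low signal.

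**Figure D4:**
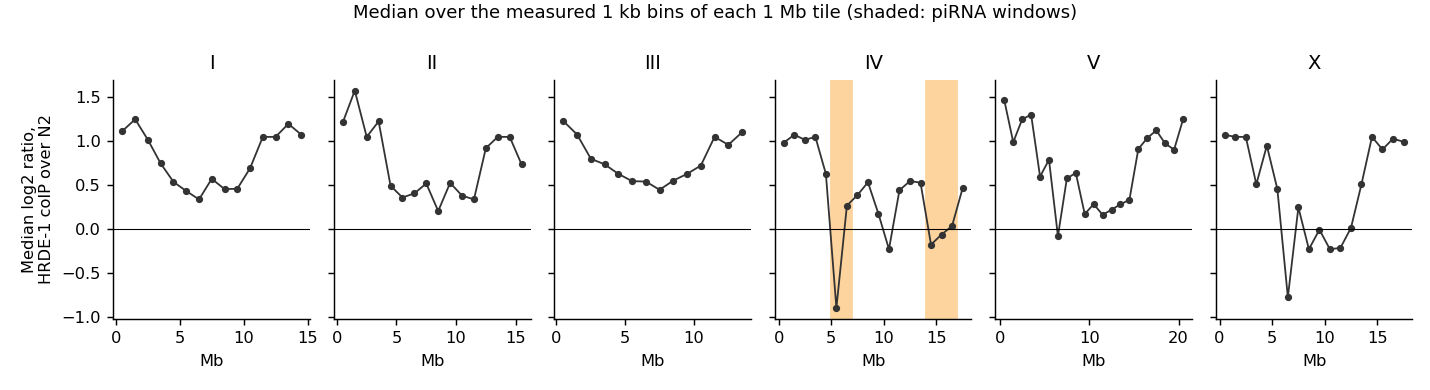
Median log2 ratio (HRDE-1 coIP over N2, library totals) over the measured 1 kb bins of each 1 Mb tile along the 6 chromosomes, with the piRNA windows of IV shaded. Outer tiles lie mostly above central ones, except on the right of IV, where the second window lies, and the lowest tile, at -0.89, is at 5 to 6 Mb of IV. Several tile medians rest on bins of very few reads.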

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

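Chosen after the data were seen were the floor subtracted, counts with totals without the top 10 bins, shares as deposited, r at a higher minimum, 1 bin per run and whole-read bins. Counts of higher and lower bins (11446 and 5326) became 25986 and 12261 at 2-fold, 4585 and 2660 at 8-fold, 6306 and 2277 at 10 times the minimum, 5575 and 2361 with 10 times the pseudocount, 5862 and 11204 with the median of ratios, and 6852 and 10724 with totals without the top 10 bins; a pseudocount 10 times smaller gave 8661 lower bins. Thresholds and minimum act by their construction, and the scalings by taking the median log2 ratio from 0.73 to 0 and to 0.13. GRTS and GRH medians fell to 0.72 and 1.15 with the median of ratios and stayed within their intervals otherwise. Over these settings the percentile among matched lists ran from 0.03 to 5.59 for GRTS and from 10.8 to 84.3 for GRH. Pearson's r was 0.558 and 0.641 with smaller and larger pseudocounts, 0.745 over all bins, 0.225 at 10 times the minimum and -0.0263 at 100 times. A minimum on the mean of both libraries lowers r by itself, and how much of the fall that gives was not tested. Arm shares of N2 and the coIP were 61.5% and 70.8% without the top 10 bins, 40.2% and 52.3% with arms as the outer 20%, and 53.6% and 71.3% as deposited. Of 108 values for 27 regions, 86 stayed within the counting interval, which has no upper limit where N2 has 0 reads, and 22 moved beyond it. Nearly all of the 22 came from scaling by the median of ratios. That scaling moved every run named for its coIP signal, every lower run and both Cer intervals. Regions picked for large ratios could not change direction under these settings. Not run were the gene lists and their alternatives, totals without structural RNA bins, which need an annotation of the file's build, and strands, which the file lacks. No paired analysis was possible because each group has 1 library. Depth limits ratios where N2 has under 3 reads.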

Other observations

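The tests below were chosen after the data were seen; for leaving out the top 10 bins, whole-read GRTS bins against the others, and 1 bin per run, the bound was written before that test's value was seen, and for the others after. The 100 highest bins of each kind differed in shape. Among the 100 highest N2 bins that were at least 4-fold lower in the coIP, the bin itself held a median of 99.4% of the signal of the 5 bins centred on it, and 67 of them held over 90%. Among the 100 highest coIP bins that were at least 4-fold higher, the median was 62.3%, and 17 held over 90%. Over all runs past the 4-fold rule the gap was smaller, with 63.8% of lower runs and 55.5% of higher runs made of a single bin. In the lists of marked runs, V 8826001 to 8837000 and V 8868001 to 8879000 were GRTS runs of 11 kb with nearly equal totals, 1217 and 1225 ppm in the coIP.

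The median measured bin was higher in the coIP by 0.73 after scaling to library totals. At 10 times the minimum it was 1.17 (1.15 to 1.21), and 0.26 (0.23 to 0.29) when that minimum was set on N2 alone, which favours N2-rich bins, so the low minimum is not the whole reason, although the size of the shift depends on how bins are chosen. Leaving the top 10 bins of either library out of both totals took the median to 0.13 (0.10 to 0.14). That misses, by a small margin, the bound of 0.1 set before this value was seen, so those bins alone do not account for the whole shift. With the top 100 bins of either library left out, 65.5% of N2 and 22.3% of the coIP, the median was -0.34 (-0.37 to -0.33). With the top 1000 left out it was -0.20. Both values lie past 0, and the change follows from the shares left out. A wider set of high bins is a candidate explanation, but these values do not test it. Enrichment by the pull-down across much of the genome was not tested either.

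GRTS bins were no higher than bins of matched mean signal, at percentile 0.57. For dilution by reads shared between repeat copies, GRTS bins with whole N2 reads (72) were compared with the 118 others. Their median was only 0.12 (-0.13 to 0.31) higher, under the bound of 0.5. However, 1 shared N2 read can place a bin among the others, and sharing in the coIP was not considered. The split does not measure how much of a bin is shared, so dilution stays open. A few long runs do not explain the low percentile, since it was 5.44 with 1 bin per run. Matching on the mean of both libraries, which picks coIP-rich bins for the comparison, may be the reason: with lists matched on N2 alone the percentile was 100.0. That value was known before the test was written, and neither matching is free of the coIP and N2 values that form the ratio, so whether HRDE-1 favours GRTS loci over other small RNA loci of like abundance stays open.

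Among the 3170 bins at 100 times the minimum, ratios spread far beyond counting noise, with an SD of log2 ratios of 2.99, 22.5 times that of Poisson draws. Carry-over of N2-like RNA at 1 fixed level stays open for the 447 bins at least 4-fold lower in the coIP: the SD of their log2 ratios was 1.58 against a median counting SD of 0.222, but without replicates the spread between libraries is unknown. A mixture of 2 normal components had a BIC lower by 1512 than 1 component, and a class of 30 bins lay between peaks of 94 and 397. This might reflect separate kinds of small RNA. However, the minimum was set on the mean of both libraries, so a bin could enter by a high value in either library alone. That choice favours ratios far from 0, and the mixture was not fitted under another minimum, so the peaks alone do not show separate kinds. Repeat copies that share reads could also make the smaller peak: only 16 of its 94 bins had whole N2 reads, and 16 of its bins had N2 values within 1% of a common value, but the ratio of peak shares, 0.256 (0.133 to 0.416), spans the bound set for it. Among whole-read bins the class between the peaks held 17 bins against 16 in the smaller peak, so these explanations cannot be told apart, and how the N2 library was prepared is unknown.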
